A study of Homo sapiens with 12 samples.

How the data were processed

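RNA of MCF-7 cells, an oestrogen receptor-positive human breast cancer line, was measured on 12 one-colour Agilent whole-genome expression arrays, 1 per sample. The labels gave 4 groups of 3 samples: Control, unfractionated heparin (UFH), dalteparin (Fragmin) and enoxaparin (Clexane). The treated samples received 40 IU/ml for 24 h in serum-free medium with lactalbumin hydrolysate. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

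The scanner intensity values were made with Agilent Feature Extraction version 9.1.3.1, per the file headers, while the submitters' processing notes name version 8.5. The deposited processed signal is a Cy3 intensity from which background was subtracted within the array, and it is not normalized between arrays. A table of the whole series held the authors' processed values as a linear ratio; its software is not given in the sources used here. From the values, this ratio is the processed signal with values under 10 set to 10, divided by a factor per array and by the probe's median over the 12 arrays, so its direction, scale and centring were settled. The medians of its columns were 0.964, 0.934 and 0.972 for Control replicates 1 to 3, 1.03, 1.06 and 1.02 for UFH, 0.990, 0.972 and 0.980 for Fragmin, and 1.04, 1.00 and 1.07 for Clexane.

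The scanner file of Control 3 was intact for 9586 of its 45015 spots. Values of 8741 probes were read from the intact spots, and 32257 were recovered from the series table by undoing its probe and array factors. Of the 6839 single-spot probes of that array that could be compared, 100% were equal within 0.001 on the log2 scale. The same step on the 10 intact arrays returned at least 99.99% of values within that tolerance. Background and outlier flags were read for Control 3 only where the spots were intact.

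The array of Clexane 3 was left out of every main result. Only 9.49% of its probes were well above background, against 68.4% to 74.3% on the 10 other arrays with complete flags, and its 75th percentile of signal was 4.24 against 894 to 2093. Its highest correlation of log2 signal with another array was 0.587, and the lowest among the other 11 was 0.962. This departs from the planned fit of 12 arrays; it was decided before any comparison was computed, and was weighed again and kept after fits with and without the array had been seen. Counts with all 12 arrays are printed beside the main counts. Clexane therefore had 2 samples.

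Signals of control spots and 187 outlier-flagged probe values were left out, and spots of a probe were averaged. Each array was divided by its 75th percentile, a common floor at log2 -6.48 of the scaled signal was set, and log2 was taken. Probes well above background on at least 3 of the 10 arrays with complete flags were kept, which left 29931 probes. For each gene the probe with the highest mean signal was used, giving 22399 genes or unnamed transcripts, 14191 of them with a reference symbol. Where another probe disagreed in direction with the probe used, in a comparison whose value for that gene is given, its value stands beside it; this was so for CASP8, CLDN5, MSMO1, SDC1, SDC4 and TFF1. Of the 41000 probes, 23434 were named through their accession, 2317 through the symbol and 1043 through a synonym in the reference table; 14206 kept the name in the file.

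A mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 2-sided) over the 11 arrays with 7 residual degrees of freedom. Values of p were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and the threshold was 0.05. Intervals are 95% intervals of the fold from this fit. A gene not well above background on every array of a group has only a bound there: the brighter group's mean was set against the higher of each dim array's lowest detected level and the probe's own signal. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

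Before the data were examined, 33 gene lists were fixed: oestrogen-induced genes, luminal and basal or mesenchymal genes, proliferation, replication histones, p53 targets, coagulation and fibrinolysis, heparan sulfate core proteins and enzymes, heparin-binding growth factors, ERK-induced transcripts, FOXO targets, NF-kB targets with cytokines, interferon response, BMP and TGF-beta targets, Wnt targets, matrix and proteases, integrins and adhesion, cholesterol synthesis, lipid storage, endoplasmic reticulum stress, hypoxia and glycolysis, NRF2 targets, metallothioneins, heat shock, apoptosis, lysosome, ribosomal proteins, oxidative phosphorylation, and markers of fibroblasts, leukocytes, endothelium and hepatocytes. Each was tested with limma's camera at a preset correlation of 0.01, which compares the list with all other genes, and adjusted over the 33 lists. Camera with an estimated correlation, and fry, were run beside it. No list call in any comparison held with an estimated correlation, and none held by fry's test of direction after adjustment over the lists. By fry's test of change in either direction 5 lists passed in UFH, 1 in Clexane, 2 in the mean of the heparins and 2 in Clexane against UFH.

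The named genes followed a rule fixed beforehand. For each heparin against Control, the 6 highest and 6 lowest past the threshold with the same sign in every within-slide difference were to be named; for the mean of the 3 heparins 10 and 10, and between heparins 4 and 4. Where under 6 passed, the 6 genes with the smallest p and a symbol were named as not past the threshold. From each list up to 3 members past the threshold were to be named. A panel of genes of coagulation, heparan sulfate, oestrogen response, growth signalling and the cell cycle was to be reported whatever its values. SERPINE1 and FGF2 of that panel did not pass the filter. The text gives only part of the panel in each comparison, and TFPI2, GPC1, HPSE and VEGFA in none. The panel values given are therefore not an unselected set. List members named beyond this rule were chosen after their values were seen.

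The 12 arrays lay on 3 slides, each with 1 array of every group, and all were scanned on 1 day, so no scan-date block was fitted. Alternatives fixed beforehand were quantile and median scaling, normexp background correction with an offset of 50, the series table, other filters and probe choices, slide and replicate blocks, fits of only the groups compared, array weights, other thresholds, and leaving out each array. Every normexp result also left out Control 3. A call lost both under normexp and without Control 3 was therefore not lost in 2 separate ways. Cyclic loess, fits without the Clexane arrays, list tests on only the groups compared or on all 12 arrays, and a correlation without Clexane 2 were added after the data were seen. The fit was tested on simulated data for UFH against Control, with 200 of the 22399 genes changed in each of 5 runs: 22.8% of 2-fold and 83.6% of 4-fold changes were recovered, with 20 and 54 false calls. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs. Genes were drawn independently in all these runs, so they do not test the preset correlation where genes vary together. The number of arrays limits the precision of every value. No genome build is named in the sources used here, so no coordinates are given.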

Results

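Heparins are anticoagulant polysaccharides given to patients with cancer. Gene expression was measured in MCF-7 breast cancer cells after 24 h with unfractionated heparin or with either of 2 low-molecular-weight heparins, dalteparin (Fragmin) and enoxaparin (Clexane), which are shorter-chained products made from it by different cleavage chemistry. All were given at 40 IU/ml, and untreated cells were the Control. The design asks what each heparin does to the transcriptome and whether the preparations differ. The comparisons used 3 Control, 3 UFH and 3 Fragmin samples and 2 Clexane samples, and 22399 genes were tested. The 75th percentile of signal was 1457 to 2093 on the Control arrays and 1358 to 1750 on the Fragmin arrays. It was 894 to 1093 on the UFH arrays and 894 to 1001 on the 2 Clexane arrays, so these groups were dimmer before scaling. The spread of a pair of replicates, as the SD of their log2 differences, was 0.30 to 0.35 for UFH, 0.46 to 0.73 for Control, 0.33 to 0.63 for Fragmin and 0.66 for Clexane. By this measure, taken over bright genes, every array was closest to an array of another group.

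UFH against Control asks what the full-length heparin mixture changes. Transcripts of NF-kB targets, cytokines and chemokines rose together in UFH: 31 of 37 were above 0, and the median was 2.50-fold higher (adjusted p = 1.25e-12 by camera, and adjusted p = 0.701 with an estimated correlation). Of the members 21 rose and 2 fell adjusted over the list alone, and over all genes 0 did. The neutrophil-attracting chemokines CXCL3 and CXCL1 rose by 4.32 ± 0.87 (SE) and 4.05 ± 1.03 on the log2 scale. The chemokines CCL20 and CCL2 rose by 3.91 ± 1.04 and 3.54 ± 0.94, and the cytokine IL1B by 3.46 ± 0.62. PTGS2, which encodes cyclooxygenase-2, was 8.73-fold higher (95% interval 4.51 to 16.9), though it was well above background on only 1 of 3 Control arrays. Control 3 was at the floor, so this fold depends partly on the floor. The other PTGS2 probe, at 1.88 on the log2 scale, had the same level in Control and Clexane, which points to the floor there too. NF-kB's own subunits NFKB1 and NFKB2 rose by 1.26 ± 0.29 and 1.72 ± 0.46, and the pathway's inhibitor TNFAIP3 by 1.57 ± 0.51. The members that fell were IL11, at -0.79 ± 0.29, and PTX3, which was not well above background on the UFH arrays and was at least 1.58-fold lower.

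Averaged over the list, the UFH arrays lay 1.49 ± 0.21 (SD, n = 3) above the Control mean on the log2 scale, from 1.33 to 1.74, and the Control arrays from -0.03 to 0.04. The 3 within-slide differences were 1.44, 1.36 and 1.69. An exact two-sided permutation test of these array means gave p = 0.1, the smallest that 3 samples against 3 allow. The p53 and adhesion lists, which were not called in UFH, gave the same p, so it does not set the NF-kB list apart. The list call held with every other normalization, block and left-out array tried at the preset correlation, with adjusted p between 3.73e-24 and 3.66e-08.

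**Figure D1:**
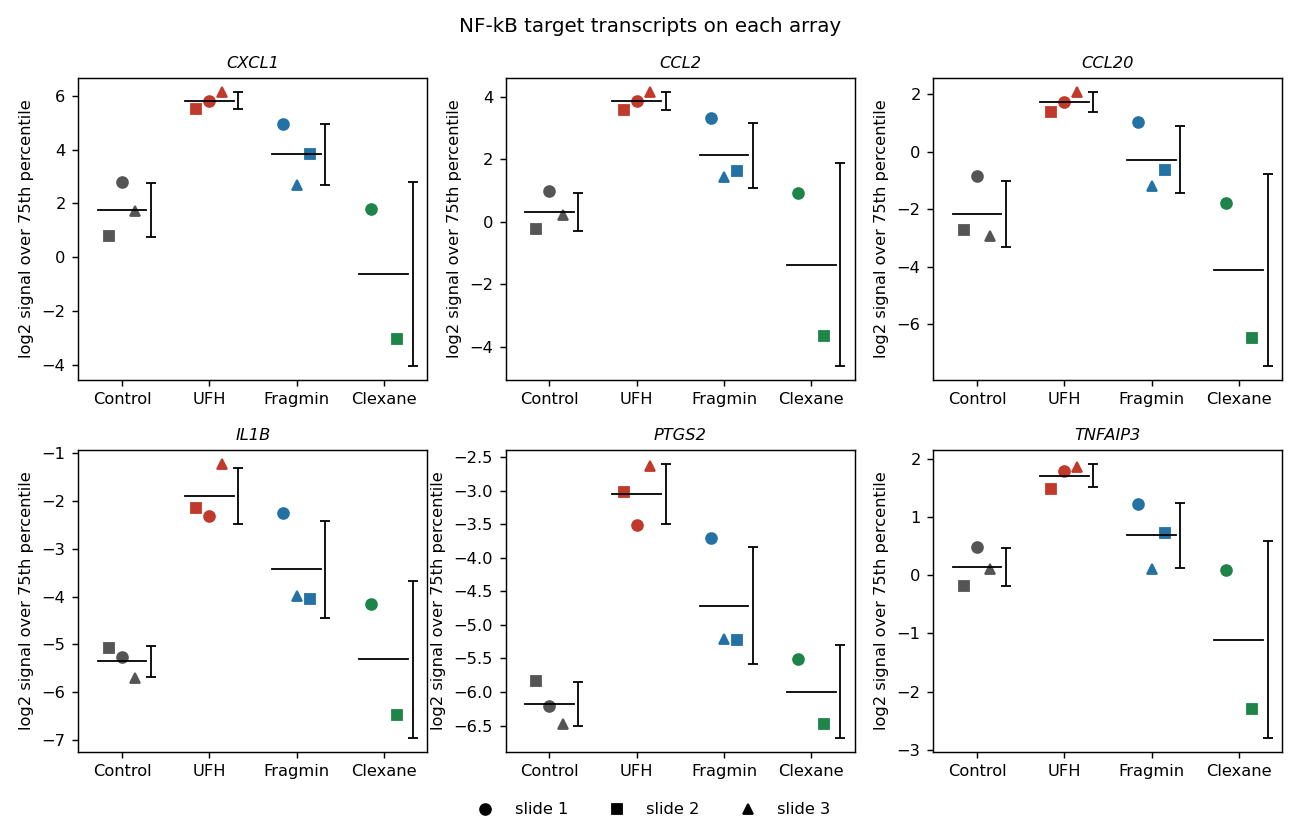
Log2 signal over the array's 75th percentile for 6 NF-kB target transcripts (y axis) on each of the 11 arrays by group (x axis); symbols mark the slide, horizontal lines the group mean and bars 1 SD. For CXCL1, CCL2 and PTGS2 all 3 UFH arrays lie above all 3 Control arrays, and Clexane 2 lies lowest, level with Control 3 at the floor for PTGS2. Clexane has 2 arrays.

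Genes of cholesterol synthesis fell in UFH: 26 of 29 were below 0 and the median change was -0.58 (adjusted p = 1.21e-08, and adjusted p = 0.701 with an estimated correlation). There, 10 fell and 0 rose adjusted over the list alone, and over all genes 0 changed. They included MSMO1 at -1.19 ± 0.36 (its other probe was at 0.84), HSD17B7 at -1.06 ± 0.21, IDI1 at -1.04 ± 0.34 and mevalonate kinase, MVK, at -0.99 ± 0.29. HMGCR, the rate-limiting enzyme, was at 0.633-fold (0.418 to 0.959, adjusted p = 0.365). The within-slide differences of the list mean were -0.15, -0.66 and -0.77. The direction was the same under quantile normalization, normexp and cyclic loess.

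ERK-induced transcripts, which include feedback inhibitors of that pathway, rose as a list in UFH, with 22 of 35 above 0 and a median of 0.30 (adjusted p = 0.00384, and adjusted p = 0.701 with an estimated correlation). None passed adjusted over the list alone or over all genes. SPRY4 was at 1.59 ± 0.49 and PHLDA1 at 1.30 ± 0.32. The members that belong to the preset panel went both ways. EGR1 was at 0.89 and MYC at 0.32, while CCND1 was at -0.49, the ERK phosphatase DUSP6 at -0.09 and FOS at -0.04. Enzymes of heparan sulfate metabolism rose with a median of 0.17 (adjusted p = 0.0256, and adjusted p = 0.701 with an estimated correlation), among them HS3ST1, a 3-O-sulfotransferase, at 1.90 ± 0.47, with 0 members past the threshold adjusted over the list alone and 0 over all genes. The apoptosis list rose with a median of 0.21 (adjusted p = 0.0282, and adjusted p = 0.701 with an estimated correlation); adjusted over the list alone CASP10 and CASP8 rose, by 2.42 ± 0.57 and 1.07 ± 0.18, and over all genes 0 did. The 2 other CASP8 probes were lower in UFH, at -0.45 and -0.49, so the direction of CASP8 rests on the probe used. The heparan sulfate call ended under normexp and without Control 3 or UFH 2, and the apoptosis call with all 12 arrays and without Control 2, with adjusted p up to 0.149 and 0.172.

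Ribosomal protein transcripts rose slightly in UFH, with 65 of 73 above 0 and a median of 1.15-fold (adjusted p = 1.07e-08, and adjusted p = 0.701 with an estimated correlation), but the direction flipped under quantile normalization (adjusted p = 0.962). Over the alternatives that list's adjusted p ran from 8.11e-10 to 0.962. Oxidative phosphorylation genes fell with a median of -0.17 (adjusted p = 0.00166, and adjusted p = 0.838 with an estimated correlation). Hypoxia and glycolysis genes fell with a median of -0.39 (adjusted p = 0.00413, and adjusted p = 0.896 with an estimated correlation), and oestrogen-induced genes with -0.22 (adjusted p = 0.0310, and adjusted p = 0.730 with an estimated correlation). No member of these 4 lists passed adjusted over the list alone or over all genes. The exact permutation p of the array means was 0.2 for the oxidative phosphorylation and hypoxia lists and 0.1 for the other 2. The hypoxia list lay at 0.65, -0.46 and -0.19 on the 3 Control arrays, and its call ended without Control 1 (adjusted p = 0.484, with 3.89e-05 to 0.484 over the alternatives). The oxidative phosphorylation call ended without UFH 3 (adjusted p = 0.154, the highest of its alternatives, down to 5.65e-06). The oestrogen call ended under cyclic loess and without Control 3, UFH 1 or UFH 3 (adjusted p up to 0.156, down to 0.00468 over the alternatives). Its members did not move as one, since TFF1, a classical oestrogen target, was at 0.58 ± 0.19 on the log2 scale (adjusted p = 0.271, with its other probe at -0.03) and CA12 at -0.63 ± 0.21.

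Endothelial markers, fixed as markers of another cell type, were called higher in UFH although the median of the 9 members was -0.05 and their mean 0.51 (adjusted p = 0.0266, and adjusted p = 0.701 with an estimated correlation). Of these 3 rose adjusted over the list alone, and 0 over all genes: CLDN5, a tight junction protein, by 2.29 ± 0.29, PECAM1, not well above background on the Control arrays with a flag for it, by at least 2.07-fold, and VWF by 0.87 ± 0.21. The value of CLDN5 depends partly on the floor, where 2 of its 3 Control arrays lay, and its other probe was at -0.20 in UFH. The call ended under normexp, under cyclic loess and without Control 2 or UFH 3, with adjusted p up to 0.171. Leukocyte, fibroblast and hepatocyte markers were not called, with medians of 0.09, 0.32 and -0.17.

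Of lists that were not called in UFH, single members passed adjusted over the list alone, and 0 over all genes. In coagulation and fibrinolysis 3 of 23 rose: urokinase PLAU by 2.16 ± 0.37, the protease-activated receptor F2RL1 by 1.14 ± 0.23, and VWF. Tissue factor, F3, was at 0.902-fold (0.460 to 1.77, adjusted p = 0.903), and well above background on 1 of the 3 UFH arrays and 1 of the 2 Control arrays with a flag for it. Among heparan sulfate core proteins syndecan-4, SDC4, was 3.60-fold higher (2.14 to 6.04), while SDC1 was at 0.945-fold (0.730 to 1.22); their other probes were at 0.58 and 0.52 on the log2 scale, so the contrast rests on the probes used. In the FOXO list IRS2, FOXO1 and INSR rose by 1.49 ± 0.30, 1.33 ± 0.32 and 1.13 ± 0.31, and TRIB3 was at -1.03 ± 0.26. E-selectin, SELE, rose at least 2.04-fold among the integrin and adhesion genes, as its 3 Control arrays were at the floor, and SQSTM1 rose by 1.17 ± 0.26 in both the lysosome and NRF2 lists, and UVRAG by 0.93 ± 0.17.

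The medians of the lists with no call in UFH were -0.36 for interferon response (adjusted p = 0.0508), 0.12 for FOXO targets, -0.18 for replication histones, 0.12 for adhesion, 0.29 for luminal genes, 0.15 for p53 targets and 0.22 for Wnt targets. They were 0.05 for lysosome, 0.09 for matrix and proteases, -0.07 for basal and mesenchymal genes, 0.02 for heparan sulfate core proteins, 0.02 for heparin-binding growth factors, 0.02 for lipid storage and -0.06 for BMP and TGF-beta targets. Metallothioneins were at -0.02, NRF2 targets at -0.11, heat shock at -0.07, endoplasmic reticulum stress at -0.01, proliferation at -0.0012 and coagulation at -0.13. Adjusted p of the lists with no call lay between 0.0508 and 0.973. Median, mean and test differed in sign for the metallothionein, NRF2, heat shock, lipid storage, leukocyte, hepatocyte, coagulation and endothelial lists.

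Over all genes limma called 0 genes in UFH against Control at adjusted p under 0.05, with the smallest at 0.0825 and 2788 genes under an unadjusted p of 0.05 where 1120 were expected by chance; with all 12 arrays 0 were called and 338 were under that p. The genes of smallest p, none past the threshold, were CLDN5, by the probe used, at 4.91-fold (3.16 to 7.62), ZNF713 at 2.71-fold (2.02 to 3.62), PTGS2, the adrenergic receptor ADRA2A at 3.94-fold (2.57 to 6.06) and SELE at least 2.04-fold, each with an adjusted p of 0.0825, and ADIPOQ at 2.41-fold (1.80 to 3.21, adjusted p = 0.103). All 6 were higher within each of the 3 slides, though CLDN5 and SELE were well above background on 1 of the 2 Control arrays with a flag for them. The fold and interval of CLDN5 therefore depend partly on the floor. When only the UFH and Control arrays were fitted, 20 genes passed, all higher, and CCL2, CXCL1, IL1B, PTGS2, TNFAIP2, PLAU and CASP10 were among them; without the Clexane arrays 28 passed. In the panel ESR1 was at 1.29-fold (0.825 to 2.00), PGR at 0.866-fold (0.503 to 1.49), CCND1 at 0.714-fold (0.477 to 1.07), MKI67 at 1.32-fold (0.949 to 1.84), EGR1 at 1.85-fold (0.871 to 3.95) and ID1 at 0.560-fold (0.377 to 0.832), with adjusted p from 0.252 to 0.820.

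Fragmin against Control asks the same of dalteparin. The NF-kB list rose in Fragmin too, with 35 of 37 members above 0 and a median of 1.60-fold (adjusted p = 1.04e-12, and adjusted p = 0.500 with an estimated correlation), though 0 members passed adjusted over the list alone or over all genes. CXCL1 was at 2.07 ± 1.03 on the log2 scale, CCL20 at 1.90 ± 1.04, IL1B at 1.92 ± 0.62 and PTGS2 at 1.46 ± 0.43. The Fragmin arrays averaged 0.92 ± 0.38 (SD, n = 3) over the list, at 1.32, 0.56 and 0.89, and within slides Fragmin lay 1.33, 0.92 and 0.52 above Control. The exact two-sided permutation p was 0.1, the smallest possible. Cholesterol synthesis fell, with 29 of 29 members below 0 and a median of -0.24 (adjusted p = 1.28e-06, and adjusted p = 0.500 with an estimated correlation), and 0 members passed adjusted over the list alone or over all genes. Both calls held with every other normalization, block and left-out array tried at the preset correlation. The exact permutation p of the array means was 0.3 for cholesterol synthesis, and 0.1 for the adhesion list, which was not called.

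Smaller list changes in Fragmin went both ways. Ribosomal proteins rose with a median of 0.14 and 72 of 73 above 0 (adjusted p = 2.53e-09, and adjusted p = 0.500 with an estimated correlation), and that call ended under quantile normalization and normexp (adjusted p = 0.240 and 0.0994, with 3.51e-10 to 0.240 over the alternatives). NRF2 targets, matrix genes, heat shock and apoptosis rose with medians of 0.22, 0.13, 0.20 and 0.17, and proliferation fell with -0.14 (adjusted p = 0.500 with an estimated correlation for each). Of these 5, only the proliferation call held in every other setting at the preset correlation, with adjusted p up to 0.0489. The exact permutation p of the proliferation array means was 0.2. Hypoxia and glycolysis genes fell with -0.28 (adjusted p = 4.57e-05, and adjusted p = 0.622 with an estimated correlation), but the call ended without Control 1 (adjusted p = 0.548). Fragmin 3 lay at -1.22, and without it the direction turned (adjusted p = 0.979, with 2.66e-13 to 0.979 over the alternatives). Endothelial markers were called higher (adjusted p = 0.00773, and adjusted p = 0.500 with an estimated correlation), a call that ended under normexp and without Control 3 (adjusted p = 0.120 and 0.139, down to 0.00041 over the alternatives). In it CLDN5 and VWF rose by 1.35 ± 0.29 and 0.93 ± 0.21 adjusted over the list alone, though the other CLDN5 probe was at -0.47. By the same adjustment F2RL1 rose by 0.89 ± 0.23 and the heparan sulfate polymerase EXT1 by 0.72 ± 0.16, and over all genes 0 members of these lists passed.

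For Fragmin limma called 0 genes over all genes, the smallest adjusted p was 1, and 613 genes were under an unadjusted p of 0.05 where 1120 were expected; with 12 arrays 0 were called and 73 were under that p. The 6 of smallest p, each with an adjusted p of 1, were the tubulin-binding TPPP3 at 2.97-fold (1.99 to 4.45), RGCC at 0.97 ± 0.17 on the log2 scale, the ciliary CFAP52 at 1.87-fold (1.45 to 2.41), SYNE1 at 2.12-fold (1.55 to 2.89), the orphan receptor GPRC5B at 3.25-fold (1.98 to 5.34) and ADRA2A at 2.64-fold (1.72 to 4.06). Each was higher within all 3 slides; CFAP52 was well above background on 1 of the 2 Control arrays with a flag for it. Of the panel, each again with an adjusted p of 1, PLAU was at 2.16-fold (1.22 to 3.85) and SDC4 at 1.77-fold (1.05 to 2.96). At the same adjusted p, IRS2 was at 1.70-fold (1.08 to 2.68) and tissue factor pathway inhibitor, TFPI, at 1.45-fold (1.03 to 2.05). These intervals lay above 1, but the panel did not rise as one. On the log2 scale MYC was at 0.75 and CDKN1A at 0.55, while FOS was at -0.75, EGR1 at -0.31, HMGCR at -0.19 and MKI67 at -0.0031.

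Clexane against Control rests on 2 arrays that lay far apart. The NF-kB list averaged 0.38 on Clexane 1 and -2.00 on Clexane 2, and 29 of 37 members were below 0 in the comparison, with a median of -0.84 (adjusted p = 1.16e-07, and adjusted p = 0.610 with an estimated correlation). Without Clexane 2 the list was called in the opposite direction (adjusted p = 0.0360, with 4.29e-24 to 0.0360 over the alternatives), and 0 members passed adjusted over the list alone or over all genes. On Clexane 2 the 7 members CCL5, CCL20, CSF3, CXCL8, CXCL10, IL1B and PTGS2 were at the floor. Ribosomal proteins rose, with 70 of 73 above 0 and a median of 1.26-fold (adjusted p = 8.80e-27, and adjusted p = 0.610 with an estimated correlation); the Clexane arrays were at 0.46 and 0.24, and the call ended under quantile normalization (adjusted p = 0.0575, the highest over the alternatives, down to 1.85e-30). RPS2 was at 0.85 ± 0.21 and RPS10 at 0.70 ± 0.18, while the 5 other RPS10 probes were at 0.07 to 0.42.

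A further 5 lists fell in Clexane. Cholesterol synthesis had 27 of 29 members below 0 and a median of -0.35 (adjusted p = 1.27e-07, and adjusted p = 0.610 with an estimated correlation), but lay at 0.01 on Clexane 1 and -0.65 on Clexane 2, and the call ended without Clexane 2 (adjusted p = 0.569, with 1.72e-10 to 0.569 over the alternatives). Interferon response fell with a median of -0.48 (adjusted p = 0.793 with an estimated correlation), its Control arrays ranging from -0.55 to 0.62 and the within-slide differences at 0.36 and -0.69. Oxidative phosphorylation, oestrogen-induced genes and metallothioneins fell with -0.10, -0.19 and -0.33 (adjusted p = 0.798, 0.610 and 0.798 with an estimated correlation), and each of these 3 calls also ended without Clexane 2, the last 2 in other settings too. Without that array metallothioneins turned direction (adjusted p = 0.415, with 6.41e-06 to 0.477 over the alternatives). No member of the 5 lists passed adjusted over the list alone or over all genes.

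Limma called 0 genes for Clexane over all genes, with the smallest adjusted p at 0.0594 and 865 genes under an unadjusted p of 0.05 where 1120 were expected; with 12 arrays 0 were called and 645 were under that p. The 6 named genes of smallest p, each with an adjusted p of 0.948, were the secretoglobin SCGB1D1 at 3.99-fold (2.25 to 7.09), MAB21L2 at 2.29-fold (1.61 to 3.25), the cGMP phosphodiesterase PDE5A at 1.69-fold (1.30 to 2.19), LINC00526 at 2.95-fold (1.69 to 5.14), ZNF713 at 1.86-fold (1.34 to 2.57) and NAA25, an acetyltransferase subunit. LINC00526 was well above background on 1 of the 2 Control arrays with a flag for it. NAA25 was not well above background on the 2 Clexane arrays and was at least 2.56-fold lower. TFF1 was at 1.66-fold (1.20 to 2.30, adjusted p = 0.948), while PLAU was at 0.870-fold (0.457 to 1.66) and SDC4 at 1.20-fold (0.671 to 2.14). The other probes of TFF1 and SDC4 were at 0.22 and -0.59 on the log2 scale.

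**Figure D2:**
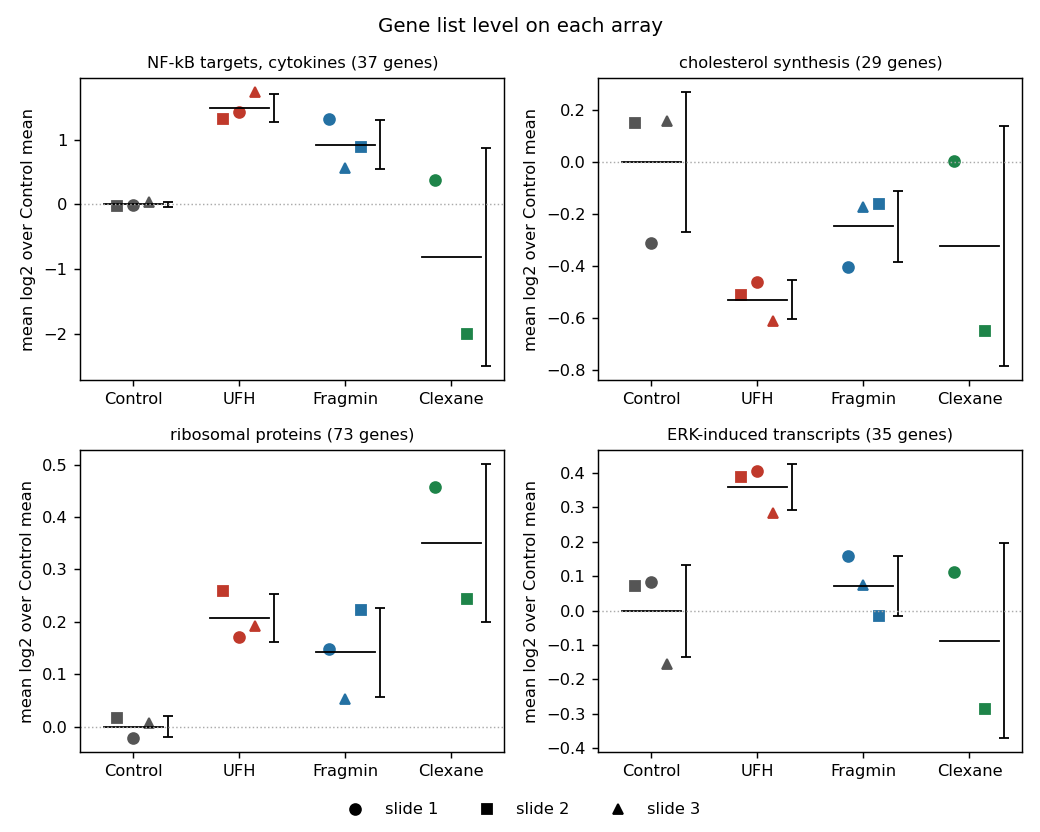
Mean log2 level of 4 gene lists relative to the Control mean (y axis) on each of the 11 arrays by group (x axis); symbols mark the slide, horizontal lines the group mean and bars 1 SD. The NF-kB list lies at 1.33 to 1.74 on the UFH arrays, 0.56 to 1.32 on the Fragmin arrays and at 0.38 and -2.00 on the Clexane arrays; the direction of the ribosomal list in UFH flipped under quantile normalization.

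The mean of the 3 heparins against Control gives their average change, which each heparin need not share. On the NF-kB list the group means were 1.49 for UFH, 0.92 for Fragmin and -0.81 for Clexane. On cholesterol synthesis Clexane 1 lay at 0.01. Cholesterol synthesis fell, with 28 of 29 members below 0 and a median of -0.40 (adjusted p = 5.64e-11, and adjusted p = 0.846 with an estimated correlation), and that call held with every other normalization, block and left-out array tried at the preset correlation. Ribosomal proteins rose with a median of 1.18-fold (adjusted p = 7.63e-20, and adjusted p = 0.846 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.331, with 7.09e-21 to 0.331 over the alternatives). The NF-kB list rose with a median of 0.36 (adjusted p = 0.000202, and adjusted p = 0.862 with an estimated correlation), and that call ended without Clexane 1 (adjusted p = 0.598, with 9.67e-18 to 0.598 over the alternatives). PTGS2 rose adjusted over the list alone, and likewise CLDN5, VWF and PECAM1 rose among endothelial markers, F2RL1 and VWF among coagulation genes, and SERPINA1 fell by 0.70 among hepatocyte markers; over all genes 0 did. The other CLDN5 probe was at -0.37.

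The other lists called for the mean were oxidative phosphorylation (-0.11), hypoxia and glycolysis (-0.30), oestrogen-induced genes (-0.20) and interferon response (-0.21), all lower (adjusted p = 0.862 for each with an estimated correlation), and endothelial markers (0.16), higher (adjusted p = 0.846 with an estimated correlation). The interferon call turned direction under normexp, which also left out Control 3, and without Control 3 alone (adjusted p = 0.631 and 0.699). It also ended under quantile normalization, cyclic loess and the replicate block, and without Fragmin 1, Fragmin 2, UFH 3 or Clexane 2. The hypoxia call ended without Control 1, Fragmin 3 or Clexane 2 (adjusted p up to 0.969). The oestrogen call ended without Control 3 (adjusted p = 0.183, the highest of its alternatives, down to 0.00147), and the endothelial call under cyclic loess, normexp and without Control 2, Control 3 or Clexane 1 (adjusted p up to 0.104, down to 0.000774). Limma called 0 genes over all genes, with the smallest adjusted p at 0.767 and 1365 genes under an unadjusted p of 0.05, and with 12 arrays 0 and 141. The genes of smallest p, at that adjusted p, were RGCC at 1.88-fold (1.51 to 2.35), ADRA2A at 2.45-fold (1.71 to 3.50), TPPP3 at 2.31-fold (1.65 to 3.23), ZNF713 at 1.84-fold (1.44 to 2.34), GPRC5B at 2.70-fold (1.79 to 4.08) and the amino acid transporter SLC7A8 at 1.62-fold (1.31 to 2.01).

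Across genes, which are not independent replicates, the log2 changes of UFH and Fragmin correlated with r = 0.543. Simulated unchanged groups set against a shared simulated control gave 0.501. The simulation gave every group the same spread, although the SD between replicates was 0.46 to 0.73 for Control and 0.30 to 0.35 for UFH. The covariance exceeded the simulated one by 0.0137. For UFH and Clexane r was 0.470 against 0.447, with a covariance difference of 0.0178, and for Fragmin and Clexane it was 0.120 against 0.447, with -0.0416. Without Clexane 2 the values with Clexane moved to 0.311 for UFH, where unchanged groups gave 0.352, and 0.355 for Fragmin, where they gave 0.354, with covariance differences of 0.0057 and -0.0083. Part of any excess may come from the shared controls, since 3 Control arrays cannot be split and their wider spread was not simulated. No gene was called in either of any pair, so there was no overlap of calls to test.

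Fragmin against UFH compares the short-chained dalteparin with unfractionated heparin at the same units and time. The NF-kB list was lower in Fragmin than in UFH, with 27 of 37 members below 0 and a median of 0.683-fold (adjusted p = 0.000371, and adjusted p = 0.738 with an estimated correlation), and 0 members passed adjusted over the list alone or over all genes. Within slides the list mean differed by -0.10, -0.44 and -1.17, and the exact two-sided permutation p was 0.1, the smallest possible. Lists that were not called gave that p too, among them coagulation and leukocyte markers. ERK-induced transcripts were lower by the same test with a median of -0.24, and cholesterol synthesis was higher with 0.23 (adjusted p = 0.738 with an estimated correlation for both). These 3 calls held with every other normalization, block and left-out array tried at the preset correlation, as did that of basal and mesenchymal genes, which were higher with a median of 0.35 (adjusted p = 0.738 with an estimated correlation).

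Other lists differed between Fragmin and UFH with less constancy. Interferon response was higher in Fragmin by 0.52 and that call ended without Fragmin 3, which lay at 1.14 (adjusted p = 0.395, with 2.67e-07 to 0.395 over the alternatives; adjusted p = 0.738 with an estimated correlation). Heat shock, NRF2 targets and oxidative phosphorylation were higher by 0.30, 0.22 and 0.10, and proliferation, luminal and fibroblast genes lower at -0.10, -0.23 and -0.34. With an estimated correlation the adjusted p was 0.788 for oxidative phosphorylation and 0.738 for the 5 others, and each of the 6 calls ended in at least 1 other setting. Ribosomal proteins were lower at -0.06 (adjusted p = 0.825 with an estimated correlation), which flipped under quantile normalization and normexp (adjusted p = 0.405 and 0.226). CASP8 fell by 0.85 and SELE fell by 0.93 adjusted over the list alone, and over all genes 0 did. The 2 other CASP8 probes were higher in Fragmin, at 0.64 and 1.39, and SELE was at the floor on 1 of 3 Fragmin arrays, so its value depends partly on the floor.

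Limma called 0 genes between Fragmin and UFH over all genes, with the smallest adjusted p at 0.520 and 1134 under an unadjusted p of 0.05 where 1120 were expected, and with 12 arrays 0 and 49. SELE was at 0.527-fold (0.421 to 0.659), ZNF713 at 0.454-fold (0.339 to 0.609) and ADIPOQ at 0.470-fold (0.352 to 0.627) at that adjusted p. CASP8 by the probe used was at 0.557-fold (0.419 to 0.739), CC2D2B at 0.550-fold (0.397 to 0.762) and SCRT2 at 0.541-fold (0.384 to 0.761), with an adjusted p of 0.759. PLAU was at 0.485-fold (0.273 to 0.863) and SDC4 at 0.491-fold (0.292 to 0.824, with its other probe at -0.09 on the log2 scale), while the intervals of EXT1 (0.864 to 1.43), HMGCR (0.913 to 2.09) and TFF1 (0.564 to 1.01) each held 1. These intervals leave room for differences of either kind, so they do not show that the preparations act alike.

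Clexane against UFH compares enoxaparin with unfractionated heparin and rests on the same 2 Clexane arrays. The NF-kB list was lower in Clexane, with 33 of 37 members below 0 and a median of 0.268-fold (adjusted p = 1.50e-34, and adjusted p = 0.128 with an estimated correlation). In it 26 fell and 2 rose adjusted over the list alone, and over all genes 0 did. CXCL1 was at -6.43 ± 1.15 on the log2 scale, CCL20 at -5.86 ± 1.16, CCL2 at -5.23 ± 1.05 and TNFAIP3 at -2.81 ± 0.57; of these CCL20 was at the floor on Clexane 2. Within the slides of Clexane 1 and Clexane 2 the list mean differed by -1.04 and -3.33, and the call held without either array. ERK-induced transcripts also fell, with a median of -0.30 (adjusted p = 1.81e-07, and adjusted p = 0.118 with an estimated correlation); SPRY4 and PHLDA1 fell by 2.92 and 2.19 adjusted over the list alone, 0 over all genes, and the call held in every other setting at the preset correlation.

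Apoptosis, p53, lysosome, metallothionein and heparan sulfate enzyme lists were lower in Clexane than in UFH, with medians of -0.10, -0.22, -0.09, -0.28 and -0.08 (adjusted p = 0.371, 0.128, 0.510, 0.745 and 0.371 with an estimated correlation). Each of these calls ended when 1 array was left out, and metallothioneins turned direction without Clexane 2 (adjusted p = 0.632, with 1.37e-06 to 0.632 over the alternatives). Ribosomal proteins were higher by 0.15 (adjusted p = 0.824 with an estimated correlation), a call that ended under quantile normalization and without Clexane 1. Adjusted over the list alone PLAU fell by 2.36, SDC4 by 1.59, HS3ST1 by 2.63, IRS2 by 1.47, FOXO1 by 1.71 and ITGB8 by 2.62, and PECAM1, not well above background in Clexane, by at least 1.97-fold; over all genes 0 did.

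Limma called 0 genes between Clexane and UFH over all genes, with the smallest adjusted p at 0.0852 and 1542 under an unadjusted p of 0.05, and with 12 arrays 0 and 948; without Clexane 1 it called 204. CLDN5 was not well above background in Clexane and at least 5.66-fold lower (adjusted p = 0.0852), by its other probe at least 1.19-fold. SELE was likewise at least 2.03-fold lower. PDE5A was not well above background in UFH and at least 2.06-fold higher in Clexane. EFNB1 was at 0.254-fold (0.164 to 0.395, adjusted p = 0.158), the transcription factor STAT5A at 0.163-fold (0.0868 to 0.307) and the Wnt receptor FZD9 at 0.206-fold (0.117 to 0.362). SELE, PDE5A, STAT5A and FZD9 had an adjusted p of 0.185.

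Clexane against Fragmin compares the low-molecular-weight products. The NF-kB list was lower in Clexane, with 35 of 37 members below 0 and a median of 0.321-fold (adjusted p = 1.24e-22, and adjusted p = 0.408 with an estimated correlation). Here 19 fell adjusted over the list alone, and over all genes 0 did; CXCL1 was at -4.45 ± 1.15, CXCL10, at the floor on Clexane 2, at -4.13 ± 1.13 and ICAM1 at -2.02 ± 0.65. Within the slides of Clexane 1 and Clexane 2 the list mean differed by -0.93 and -2.89. Interferon response fell too, with 31 of 32 members below 0 and a median of -0.65 (adjusted p = 5.12e-09, and adjusted p = 0.594 with an estimated correlation), though Fragmin 3 stood apart at 1.14 and the within-slide differences were 0.09 and -1.90. Both calls held in every other setting at the preset correlation.

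NRF2 targets, metallothioneins, ERK-induced transcripts, coagulation, apoptosis, endoplasmic reticulum stress and matrix genes were lower in Clexane than in Fragmin, with medians of -0.23, -0.47, -0.25, -0.32, -0.09, -0.12 and -0.10 (adjusted p = 0.594, 0.594, 0.423, 0.423, 0.594, 0.594 and 0.594 with an estimated correlation). Each of the 7 calls ended without Clexane 2, and the last 2 turned direction (adjusted p = 0.274 and 0.623). The p53 list was lower at -0.14 and ribosomal proteins higher at 0.20 (adjusted p = 0.408 and 0.594 with an estimated correlation), and both calls ended without Clexane 1 and in other settings. Among endothelial markers CLDN5 fell adjusted over the list alone, though its other probe was at 0.02, and over all genes no list member passed.

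Over all genes limma called 2 transcripts between Clexane and Fragmin, both higher in Clexane and both without a gene symbol, with an adjusted p of 0.0345; 1222 were under an unadjusted p of 0.05, and with 12 arrays 0 were called and 1044 were under that p. They were the transcript of probe A_24_P874007, by 1.82 ± 0.19 on the log2 scale and well above background on 2 of 3 Fragmin arrays, and BU607658, not well above background in Fragmin and at the floor on all 3 of its arrays, by at least 6.15-fold. Both were named after their values were seen. Both calls ended under quantile normalization and in several other settings. Of genes with a symbol none passed. CLDN5 was at least 2.94-fold lower, SCGB1D1 was at 3.41-fold (1.92 to 6.05), CIITA, the class II transactivator, at 0.188-fold (0.0854 to 0.415), KIF24 at 1.85-fold (1.37 to 2.50), PDE5A at 1.71-fold (1.32 to 2.22) and MAB21L2 at 2.01-fold (1.42 to 2.85), each with an adjusted p of 0.824. CIITA was well above background on 1 of 2 Clexane arrays, with its other probe at -0.74 on the log2 scale, and SCGB1D1 on 2 of 3 Fragmin arrays.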

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

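The tests on arrays and markers in this part were chosen only after the results were seen, except the test of signal-matched genes. The gene lists and comparisons, and the settings that the processing names as fixed beforehand, were chosen before the data were examined; the fit of 11 arrays departs from that plan. Groups had at most 3 samples, so no test for an outlying sample was run.

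The 10 spike-in control probes on the arrays, which no comparison used, gave a median signal on the array of UFH 3 that was 92.2-fold that of the Control arrays, from the 6 probes above the floor in every Control array. On the other 10 arrays of the comparisons this ratio was 0.604 to 1.74. This was noted because a signal appeared in data outside the main measurement. The 75th percentile of UFH 3 was 934, against 894 and 1093 on the other UFH arrays, and UFH 3 lay at 1.74 on the NF-kB list where these were at 1.33 and 1.42. Neither a technical nor a biological cause of the spike-in signal was tested.

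The NF-kB and cytokine list was higher on the UFH and Fragmin arrays than on the Control arrays. For dimness, the highest Clexane array, from an equally dim group, differed from the lowest UFH array by -0.94 on the log2 scale. The SD of the UFH arrays was 0.21. This cannot exclude dimness in UFH, because a lowering of the list by enoxaparin could hide a rise from dimness. That Clexane array, at 0.38, also lay above the highest Control array, at 0.04. The Fragmin arrays overlapped the Control arrays in brightness and averaged 0.88 above the highest Control array, which argues against dimness for Fragmin. RNA from leukocytes was argued against, since their 12 markers averaged -0.12 (SE 0.19, across markers and not samples) against 1.52 for the list in UFH. Of these 8 were above 0 and 4 below, none past the threshold, from CSF1R at -1.92 and HLA-DRA at -0.96 to TYROBP at 0.40 and LYZ at 0.44, the highest, with a median of 0.09. An effect shared by the arrays of a slide could not make the difference, since each slide held 1 array of every group. The lowest within-slide difference of UFH and Control was 1.36. The Control SD of 0.04 is that of list means, and single members could vary more, such as CXCL3 at -3.20, -0.60 and -3.08 on the Control arrays. An effect of the heparins stays open as a hypothesis found and tested on the same data, and so does an impurity in a preparation, which may act on NF-kB and which these arrays cannot test.

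The 2 Clexane arrays lay 2.38 apart on the same list, with Clexane 2 the lower. Its slide was argued against, since the 3 other arrays of that slide deviated from their group means by -0.079 on average. Dimness was argued against, as its 75th percentile was 1.12 times that of Clexane 1. A label exchanged within the series stays open. Clexane 2 differed from the lowest array of the other groups by -1.97 on this list, where the highest SD within a group was 0.38. Over all bright genes it was closest to Control 2. The SD of log2 differences was 0.38 with that array, 0.66 with Clexane 1 and 0.46 to 0.73 among the Control arrays. By this measure every array was closest to an array of another group, each UFH array to Fragmin 1 at 0.24 to 0.31. Such closeness therefore does not single out Clexane 2. An outside sample, a difference in the culture and a response to enoxaparin stay open, and a biological difference between the 2 samples could not be tested with 1 array each.

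Ribosomal protein transcripts were higher on the heparin arrays, though in UFH the direction flipped under quantile normalization. Genes of the same mean signal outside the list had a median change of 0.11 (SE 0.01, across genes and not samples) in the mean of the heparins. The list was at 0.23, so part of the shift may come from an offset that depends on signal. The matched shift lay between the bounds set before the test, so such an offset and a change of the transcripts cannot be told apart. Those bounds were set for the mean only. By heparin, the matched genes and the list were at 0.105 and 0.198 in UFH, 0.0948 and 0.137 in Fragmin, and 0.158 and 0.338 in Clexane. In UFH and Fragmin the matched shift would have reached the bound for an offset, and in Clexane it would not. No biological explanation was tested for it.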

How the results depend on the processing

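Cyclic loess, fits without the Clexane arrays, list tests on only the groups compared or on 12 arrays, and the correlation of responses without Clexane 2 were chosen only after the results were seen. Where an array was left out and a group kept 1 sample, that sample was assumed to vary like the other groups in the limma fit. Unless a reason is given, the cause was not tested.

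Counts of genes past adjusted p 0.05 were within 1.5 times the first count in 149 settings and moved in 42. For UFH against Control the count moved from 0 to 1 with the series table, 20 with only the groups compared, 28 without the Clexane arrays and 4386 with array weights, and ranged from 0 to 28 as single arrays were left out (28 without Clexane 1 or Clexane 2, 1 without Control 2 or Fragmin 1). The pooled spread of that fit includes the gap between the Clexane arrays. For Fragmin it was 2610 with array weights and 0 without any 1 array. For Clexane it was 1 with median scaling, 10 with no filter, and 0 to 28 as arrays were left out (28 without Clexane 1, 6 without Clexane 2). For the mean it was 2457 with array weights and 0 to 7 with an array left out (7 without Clexane 2). For Fragmin against UFH it was 17 with array weights and 0 without any 1 array. For Clexane against UFH it was 13 with no filter and 0 to 204 with an array left out (204 without Clexane 1, 9 without Clexane 2, 1 without Control 3). Array weights ran from 0.32 for Control 3 to 5.63 for Control 1, so those counts lean on few arrays.

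The 2 transcripts called between Clexane and Fragmin became 0 under quantile normalization, normexp, cyclic loess, the series table, the stricter filter, the slide block, only the groups compared, trend and robust settings, all 12 arrays and adjusted p under 0.01. The count was 10 with no filter, and 0 to 143 with an array left out (143 without Clexane 1, 7 without Clexane 2, 2 without Control 3, and 0 without any 1 of the other arrays). The series table moved the median of all genes in Clexane from 0.0258 to -0.105 against Control and from 0.0366 to -0.104 against Fragmin; with all 12 arrays these medians were -0.274 against Control, -0.217 against UFH and -0.282 against Fragmin. Changes under those settings are relative to these shifts.

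Counts of lists past adjusted p 0.05 were within 1.5 times in 118 settings and moved in 27. With camera at an estimated correlation 0 lists passed in UFH, Fragmin, Clexane, their mean, Fragmin against UFH, Clexane against UFH and Clexane against Fragmin, and with fry's test of direction 0 passed in each. With only the groups compared and an estimated correlation 0 passed in the 6 pairwise comparisons. For Clexane the count moved from 7 to 12 under normexp. With single arrays left out the counts ranged from 7 to 11 for UFH, 8 to 14 for Fragmin, 7 to 13 for Clexane (13 without Clexane 1, 11 without Control 3), 6 to 13 for the mean (13 without Clexane 2), 9 to 12 for Fragmin against UFH, 7 to 13 for Clexane against UFH (13 without Clexane 2) and 7 to 14 for Clexane against Fragmin (7 without Clexane 2).

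Of 66 list calls, 17 stayed past the threshold in the same direction in every other normalization, block and left-out array at the preset correlation. Over the settings, called lists kept direction and call in 1041 cases, lost the call in 318 and reversed in 11. Ribosomal proteins reversed under quantile normalization in UFH against Control (adjusted p = 0.962) and in Fragmin against UFH (0.405), and there under normexp too (0.226). Interferon response in the mean reversed under normexp (0.631), which left out Control 3 too, and without Control 3 alone (0.699). Hypoxia in Fragmin reversed without Fragmin 3 (0.979). Without Clexane 2, NF-kB targets in Clexane reversed (0.0360), as did metallothioneins in Clexane (0.415) and against UFH (0.632), and against Fragmin matrix genes (0.623) and endoplasmic reticulum stress (0.274). These reversals without an array follow from the levels on that array. Over the arrays left out, the adjusted p ranged from 2.66e-13 to 0.979 for hypoxia in Fragmin, 4.29e-24 to 0.0360 for NF-kB in Clexane, 6.41e-06 to 0.415 for metallothioneins in Clexane and 1.37e-06 to 0.632 against UFH, 1.41e-05 to 0.699 for interferon response in the mean, 0.000632 to 0.623 for matrix genes and 1.18e-05 to 0.274 for endoplasmic reticulum stress.

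The sample numbers do not show whether replicates with 1 number belong together. With a block for the replicate number, 0 genes passed in each comparison, 0 in place of 2 for Clexane against Fragmin included, and 12 lists in place of 7 for Clexane. Of the 66 list calls 1 ended with this block, that of interferon response in the mean (adjusted p = 0.117 by camera). In the check of this pairing, 7 of 15 pairs of arrays with 1 number correlated above 0.1 after group means were removed, from -0.29 to 0.62, and 5 of 15 pairs on 1 slide did, from -0.62 to 0.65.

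For 203 results on named genes, 70 values of 5111 crossed the threshold in the same direction, and 247 uncalled values changed sign, in 89 of the results. Without Clexane 2 the correlation of UFH and Clexane responses moved from 0.470 to 0.311 and that of Fragmin and Clexane from 0.120 to 0.355, where unchanged groups of the same sizes gave 0.352 and 0.354. Between 68.4% and 74.3% of probes were well above background on the 10 arrays with complete flags, and Control 3 had such flags only in part, which limits values of dim genes.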

Other observations

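The predictions for the splits below were written before the splits were run. Other splits of the same arrays into groups of the same sizes were fitted with limma and tested with camera. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. With a real count of 0 genes every split gives at least as many, so the gene counts could not test chance. For UFH against Control 10 of 10 splits gave as many genes (0, highest other 0) and 5 gave as many lists (10, highest other 11). For Fragmin against Control 10 of 10 gave as many genes (0, highest other 33) and 2 as many lists (10, highest other 10). For Fragmin against UFH 10 of 10 gave as many genes (0, highest other 0) and 1, the real split, as many lists (12, highest other 9). At an unadjusted p under 0.05 the real splits had 2788, 613 and 1134 genes. Of the 9 other splits of the Fragmin and Control arrays 1 called 33 genes and 8 called 0, where the real one called 0. That split set Control 1, Control 3 and Fragmin 3 against Control 2, Fragmin 1 and Fragmin 2. Control 3 and Fragmin 3 were each closest to the other over bright genes, with an SD of log2 differences of 0.42. They also lay lowest on the first principal component, the axis of largest variation (38.8%), at -68.7 and -58.6. Control 2 lay at 36.8, so this axis did not separate Control from heparin. The cause of this structure was not tested.

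For the mean of the 3 heparins 100 splits were drawn. All 100 gave at least as many genes as the real count of 0 (1365 at an unadjusted p under 0.05 by limma), which was certain with a count of 0. The highest other gene count was 22. For lists, 59 splits gave at least as many as the real 8, with 14 as the highest other. Chance could not be excluded for the list count, and the gene count could not test it. A count does not show which lists a split calls, and the splits were not compared list by list.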
